A study of Fucus vesiculosus with 12 samples.

How the data were processed

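Gene expression was measured in apical tips of the brown seaweed Fucus vesiculosus with 12 custom Agilent oligonucleotide arrays. Pieces of the alga either were or were not grazed by the isopod Idotea baltica, a crustacean herbivore, for 15 or 18 days. Per the labels, each of the 4 groups held 3 biological replicates. Every array carried the RNA of a piece labelled with Cy3. It also carried, labelled with Cy5, a common pool of RNA from 4 pieces collected before grazing began (day 0). No dye swap was among the arrays, so a difference between a sample and the pool cannot be told apart from a difference between the dyes. A comparison between samples is free of that limit because the pool was in the same dye on all 12 arrays. Per the labels' protocols, 80 ng of total RNA was amplified and labelled with a low-input kit of the array maker, with random primers added.

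The deposited scanner files gave the intensity of each spot and of its local background in both dyes, as written by Agilent Feature Extraction version 10.7.3.1, per the submitters' processing notes. The files also gave quality flags and, per the file headers, a log10 ratio of Cy5 over Cy3 after Agilent's own background and dye correction. That deposited log10 ratio had been set to 0 at 41082 of the 491796 probe spots. Of these, 38647 were not significantly above background in either dye. The series' value table equalled the deposited log10 ratio at all 491796 spots within a tolerance of 1e-06, so its scale and direction were known, and it served as 1 alternative with it. Its column medians were 0 on all arrays except ungrazed day 15 replicate 3, where the median was -0.0033. No centring beyond Agilent's was seen.

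Each array held 42400 spots, of which 1417 were controls and 40983 were probes, with 1 spot per probe. The files identified each probe by a number alone and held no gene names or descriptions: the annotation column differed from the probe identifier for 0 probes. Gene names were not used here, and the gene lists fixed in advance could not be applied. Spot medians were used in place of spot means, which had been planned, because the files held medians.

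Background was corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50. Each array was normalized within itself by loess, with control spots and flagged outlier spots given no weight, and the outlier spots were left out of the fits. Values are log2 ratios of the sample (Cy3) over the day 0 pool (Cy5). Probes well above background in Cy3 on at least 3 of the 12 arrays were tested, which kept 34311 and left out 6672.

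Replicates were compared before they were averaged. For each pair of arrays the spread of the log2 difference was computed in each dye over the 22636 probes well above background on all arrays, as a scaled median absolute deviation. The pool, being 1 RNA, gives the technical spread between the same 2 arrays. Its spread ranged from 0.0859 to 0.293. In 2 pairs of the same group the sample differed by no more than the pool. These pairs, replicates 1 and 2 of the ungrazed day 18 group and replicates 1 and 2 of the grazed day 18 group, were averaged and each counted as 1 sample. This left 10 samples: 3 in each day 15 group and 2 in each day 18 group. The planned analysis counted 12 arrays. The averaging was decided after the data were examined, and the counts with 12 arrays are given beside the others. The labels do not say whether pieces came from separate plants, so p-values measure the spread between these samples, which may be technical.

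All samples entered 1 limma model with a mean for each group and a shared variance per probe, moderated by empirical Bayes. The residual degrees of freedom were 6, with 2.25 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a change. The comparisons were grazed against ungrazed at each day, over both days, and as a difference between the days. Day 18 was also compared with day 15 within ungrazed and within grazed pieces, and both kinds of pieces with the pool. An exact permutation test within days compared whole profiles. The design and the settings first listed were chosen before the data were examined. Probes named in the text were the 2 with the highest and the 2 with the lowest log2 change per grazing comparison, among those past the threshold where there were at least 2. Probes outside that rule are said to be so. Where a probe was not well above background on any array of a group, its fold is given as a lower bound. The bound compares the Cy3 channel after loess and quantile normalization of mean intensity, after quantile normalization without loess, and without normalization, and the lowest of the 3 is given. The last 2 were added after the data were examined. The bound is open to dye bias.

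The procedure was tested on simulated data with 200 of 34311 probes changed. The simulated noise was independent between probes and samples, with the same spread in all groups. In the real data the median SD within groups ran from 0.10 to 0.34, so the rates below hold for such noise alone. At a log2 change of 2 it recovered 61% at day 15, 46% at day 18 and 81% over both days. At a log2 change of 4 it recovered 92%, 85.5% and 97.5%, in the same order. Between 4 and 16 unchanged probes were called in these runs. The number of arrays limits the precision.

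The arrays lay on 4 slides. Ungrazed day 15 replicate 1 lay on slide 30. The other ungrazed day 15 arrays and grazed day 15 replicates 1 and 2 lay on slide 31. Grazed day 15 replicate 3 shared slide 32 with the 3 ungrazed day 18 arrays, and the 3 grazed day 18 arrays lay on slide 33. Alternatives covered the background correction, Agilent's own ratios, the normalization within and between arrays and the Cy3 channel alone. Others covered the filter on dim probes, the groups in the fit, slide as a block, the variance model, array weights and leaving out each sample. A planned block on replicate number was run only with 12 arrays counted, a form chosen after the data were examined, since an averaged pair carries 2 numbers. Counting all 12 arrays, as planned, became an alternative once the pairs were averaged. Alternatives added after the data were examined averaged a further pair, averaged neighbouring probe numbers and entered or restricted the spike-in ratio. That ratio is the median log2 Cy3 over Cy5 of the control transcripts added to the labelling reactions, which falls as more algal RNA is labelled in the sample.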

Results

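The arrays compared apical tips of Fucus vesiculosus that had or had not been grazed by Idotea baltica, a design that asks which seaweed transcripts change under grazing. Sample signal differed more between arrays than pool signal. The median Cy3 intensity ranged from 74 on ungrazed day 15 replicate 1 to 381 on ungrazed day 18 replicate 3, and the median Cy5 intensity from 165 to 232. Between 59.2% and 83.4% of probes were well above background in Cy3, against 75.5% to 83.7% in Cy5. No probe spot was saturated. Raw log2 intensities of the pool correlated across probes at 0.983 to 0.998 between arrays, and those of the samples at 0.743 to 0.994, as a common pool in Cy5 would give. Control transcripts added to the labelling differed in their log2 Cy3 over Cy5 ratio from -2.13 on ungrazed day 15 replicate 3 to 4.78 on grazed day 15 replicate 1.

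Among arrays of the same group, 2 pairs differed by less than the technical spread of the pool and were counted as 1 sample each. In ungrazed day 18 replicates 1 and 2, the sample channel had a spread of 0.0716 log2 units and the pool channel 0.0859. Their ratio was 0.834 (95% bootstrap interval over probes 0.816 to 0.851). In grazed day 18 replicates 1 and 2, the spreads were 0.1001 and 0.1049, with a ratio of 0.954 (0.936 to 0.972). The next closest pair, ungrazed day 15 replicates 1 and 2, lay on different slides and had a ratio of 1.11 (1.09 to 1.13), so it was kept as 2 samples. In the 10 same-group pairs that were not averaged, the spread of the sample channel ranged from 0.226 to 0.840.

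**Figure D1:**
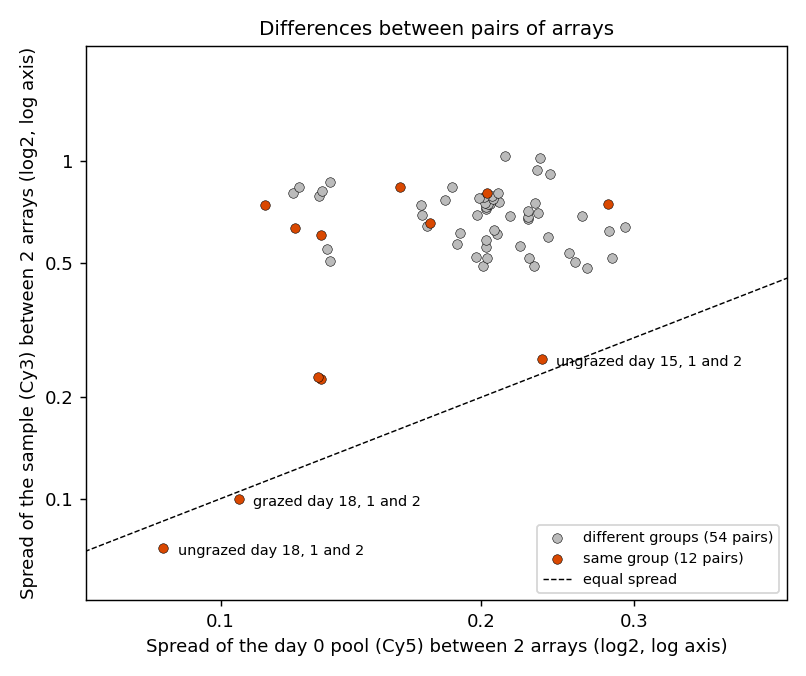
Spread of the log2 difference between 2 arrays in the sample channel (Cy3, vertical log axis) against that in the pool channel (Cy5, horizontal log axis), 1 point per pair of arrays; orange points are pairs within a group and the dashed line marks equal spread. Only 2 pairs, both at day 18, lie under the line, at ratios of 0.834 and 0.954.

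The samples did not separate by grazing as a whole. The first principal component held 49.0% of the variance and the second 16.2%. Grazed day 18 samples lay at one end of the first component and ungrazed day 18 samples toward the other, with the day 15 samples of both groups spread between and beyond them. Within groups, log2 ratios correlated across probes at -0.09 to 0.86 in ungrazed day 15 samples and at 0.13 to 0.23 in grazed day 15 samples. The correlation was 0.65 between the 2 ungrazed and 0.95 between the 2 grazed day 18 samples. An exact permutation test of the whole profile gave p = 0.8 at day 15 (smallest possible p 0.1), p = 0.333 at day 18 (the smallest possible) and p = 0.133 over both days, with 16 of 120 assignments as large. Neither day could reach a p under 0.05 on its own.

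**Figure D2:**
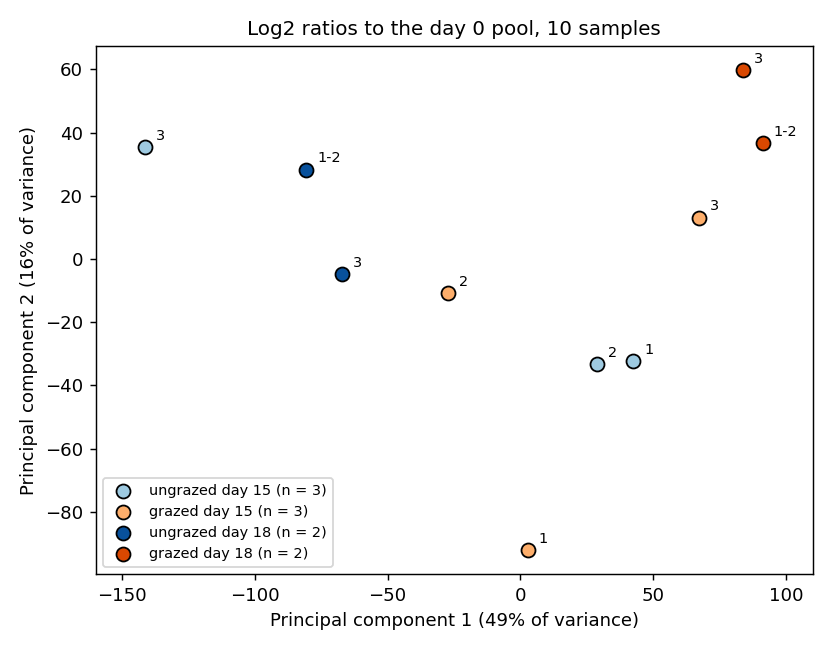
The 10 samples on the first 2 principal components of their log2 ratios to the day 0 pool, with 49% and 16% of the variance; numbers beside the points are replicates and colours are groups. The 2 grazed day 18 samples lie apart from the 2 ungrazed day 18 samples, while grazed and ungrazed day 15 samples overlap.

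At day 18, 38 of 34311 probes differed between grazed and ungrazed tips, 21 higher and 17 lower in grazed tips. Of the 38, 7 were not well above background on any ungrazed day 18 array and 3 on any grazed one, so only a bound holds for these 10. The absolute log2 changes of the other 28 ranged from 1.54 to 5.82, with a median of 2.34, and the median over all 38 was 2.43 with the 10 at their bound in Cy3. The 21 probes that rose lay at a median of -0.18 log2 units from the day 0 pool in ungrazed and 2.89 in grazed day 18 samples. The 17 that fell lay at 0.80 and -1.54. For 16 of the rising and 13 of the falling probes, the grazed mean was the one farther from the pool. Of the 38 probes, 21 were well above background on all 6 day 15 arrays and 2 on none.

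The highest fitted log2 changes were those of CUST_33802_PI408257168 and CUST_33803_PI408257168. CUST_33802_PI408257168 stood at 6.90 ± 0.61 log2 units above the pool in grazed and 0.01 ± 0.02 in ungrazed day 18 samples (SD, n = 2 each). Its log2 change was 6.89 (SE 0.30, limma adjusted p = 0.00016). CUST_33803_PI408257168 stood at 6.88 ± 0.61 and 0.01 ± 0.15, a change of 6.87 (SE 0.33, limma adjusted p = 0.00026). Neither was well above background on any ungrazed day 18 array. In Cy3 they were at least 1030-fold and at least 945-fold higher in grazed tips, the lowest bounds of 3 treatments of that channel (1397 and 1262 after loess and quantile normalization). With Agilent's own ratios the call of CUST_33803_PI408257168 was lost at a log2 change of 6.99 (limma adjusted p = 0.0868), while CUST_33802_PI408257168 had an adjusted p of 0.043. The pool signal of these probes rose on the same slide, from a mean of 55.2 to 1048 for CUST_33802_PI408257168 and from 64.5 to 1029 for CUST_33803_PI408257168. In all, 6 of the 38 called probes, each of them higher in grazed tips, had a pool signal that moved by over 1 log2 unit between the slides of the 2 groups. Without them, 32 called probes were left, 15 higher and 17 lower. Over all 34311 tested probes, 969 (2.82%) had a pool signal that moved as far.

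The strongest fitted falls were those of CUST_46204_PI408257168 and CUST_46205_PI408257168, both above background on all day 18 arrays. The 3 falling probes with only a bound could rank elsewhere. CUST_46204_PI408257168 stood at -4.20 ± 0.33 in grazed and 0.95 ± 1.13 in ungrazed day 18 samples (SD, n = 2 each), a log2 change of -5.15 (SE 0.57, limma adjusted p = 0.0266). CUST_46205_PI408257168 stood at -3.86 ± 0.27 and 0.95 ± 1.07, a change of -4.81 (SE 0.56, limma adjusted p = 0.0355). Both calls were lost without 3 of the 4 day 18 samples: adjusted p (limma) was 0.0994 and 0.13 without ungrazed replicates 1-2, 0.307 and 0.307 without grazed replicates 1-2, and 0.48 and 0.551 without grazed replicate 3. Over the 4 fits that left out a day 18 sample the log2 changes ran from -5.95 to -4.36 and from -5.57 to -4.05. They were also lost with ungrazed day 15 replicates 1 and 2 averaged (0.0872 and 0.0911), and with only probes above background on all 12 arrays (0.0699 for both). CUST_46205_PI408257168 lost its call with median centring (0.0581) and with the spike-in ratio as a covariate (0.0553) as well. The files do not pair probe identifiers with genes, so no function is given for any probe.

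With each of the 12 arrays counted as a sample, 5453 probes passed at day 18, 3379 higher and 2074 lower, among them all 38. With the pairs averaged, 4406 passed with only the groups compared in the fit (3249 higher, 1157 lower), 4848 with array weights (3194 higher, 1654 lower) and 1767 without the 3 samples of highest spike-in ratio (1506 higher, 261 lower). The 3 grazed day 18 arrays shared 1 slide, which held no other group, so slide and grazing were confounded at day 18. With slide as a random block 71 passed, 31 higher and 40 lower. The estimated correlation within slides was -0.06, so this block allowed for no shared slide effect and cannot separate slide from grazing. Agilent's own ratios called 40 probes, 11 higher and 29 lower, of which 12 were among the 38. The Cy3 channel alone called 39, 17 higher and 22 lower, and median centring in place of loess called 15. With ungrazed day 15 replicates 1 and 2 averaged too, 11 passed, 8 higher and 3 lower. With only probes above background on all 12 arrays, 1 passed, lower in grazed tips.

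**Figure D3:**
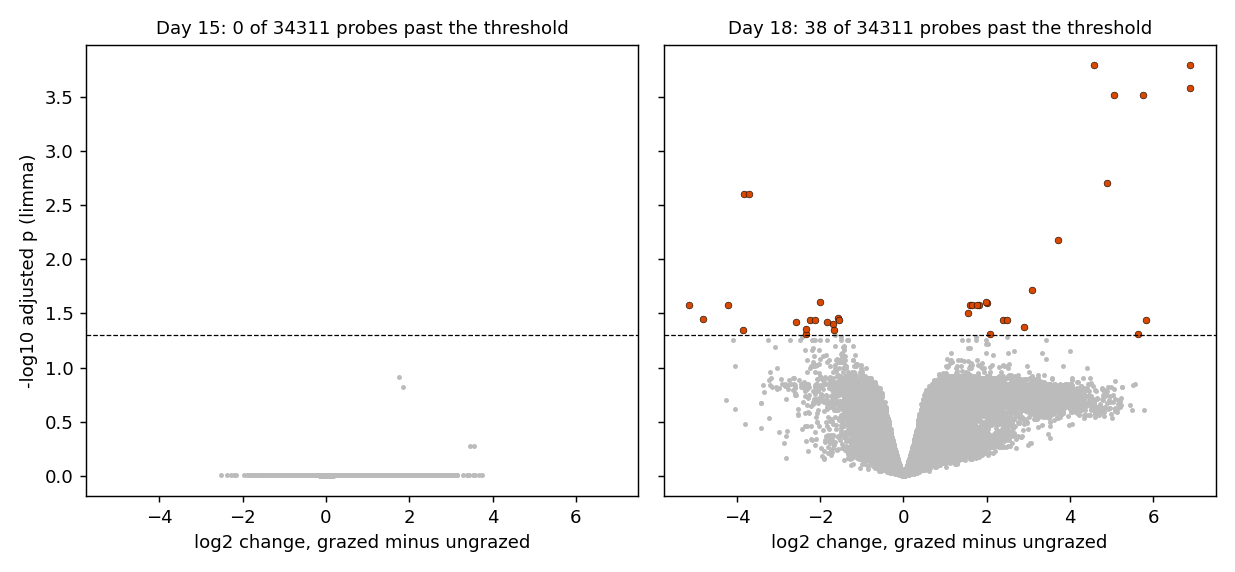
Adjusted p (limma, vertical axis as -log10) against log2 change, grazed minus ungrazed, for 34311 probes at day 15 and day 18; orange points passed an adjusted p of 0.05, marked by the dashed line. At day 15, 0 probes passed and at day 18, 38.

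At day 15, 0 probes differed between grazed and ungrazed tips after adjustment in limma. The smallest adjusted p was 0.121, and 1337 probes had an unadjusted p under 0.05, where chance alone gives 1716. With 12 arrays counted, 2 probes passed, both higher in grazed tips. These were CUST_44292_PI408257168, with a log2 change of 1.84, and CUST_44293_PI408257168, with 1.75, named because they were the only ones and after their values were seen. With the pairs of arrays averaged and neighbouring probe numbers averaged as well, 1 unit passed, higher in grazed tips. The largest positive differences were those of CUST_48743_PI408257168 (3.73, SE 0.93) and CUST_47995_PI408257168 (3.68, SE 0.98). The largest negative ones were those of CUST_1472_PI408257168 (-2.53, SE 1.31) and CUST_6513_PI408257168 (-2.37, SE 0.59). All 4 had a limma adjusted p of 0.981. CUST_48743_PI408257168 stood at 0.43 ± 1.38 in grazed and -3.30 ± 1.59 in ungrazed day 15 samples (SD, n = 3 each). Within slide 31, which held both groups, and with slide as a fixed block, 0 probes passed. Both fits compare ungrazed replicates 2 and 3 with grazed replicates 1 and 2, so they are 1 comparison of few samples. In both, the changes of the 4 probes were 2.86, 2.69, -0.88 and -1.98, in the order above.

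At day 15, 1028 probes (3.00%) differed by a log2 of at least 1, 877 higher and 151 lower in grazed tips, against 5092 (14.8%) at day 18, 3985 higher and 1107 lower. Across probes, which are not independent replicates, the day 15 and day 18 changes correlated at r = 0.318 (rho = 0.256), and 59.2% shared a sign. Of the 10 ways to split the 6 day 15 samples, 7 gave a correlation at least as large in size, the highest other being 0.741. Of the probes that rose at day 18, 18 of 21 had the same direction at day 15, at a median log2 of 0.23. Of those that fell, 6 of 17 did.

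**Figure D4:**
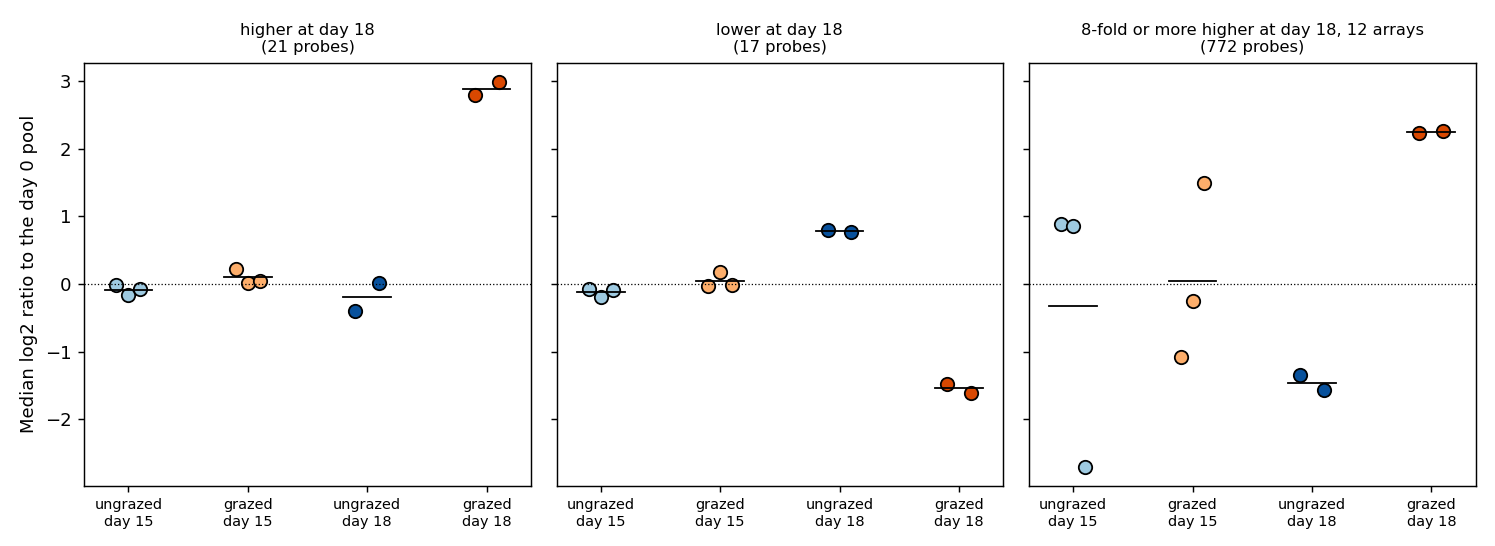
Median log2 ratio to the day 0 pool in each sample (points; bars are group means) for the 21 probes higher and the 17 lower in grazed tips at day 18, and for the 772 probes at least 8-fold higher when 12 arrays were counted. The medians of the first 2 sets lie near 0 in all day 15 samples, while that of the third ranges from -2.70 to 0.88 within the ungrazed day 15 group. The first 2 sets were called with a variance shared with the day 15 samples, which favours probes that vary little there.

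Over both days, 9 probes differed, 8 higher and 1 lower in grazed tips, against 1152 with 12 arrays counted. The 8 were among the 21 that rose at day 18 and the 1 among the 17 that fell. With 0 probes called at day 15, these calls do not show a change on both days. Array weights gave 85, and only probes above background on all 12 arrays gave 0. CUST_33802_PI408257168 and CUST_33803_PI408257168 had mean changes of 3.61 (SE 0.19, limma adjusted p = 0.00118) and 3.55 (SE 0.22, limma adjusted p = 0.00157). Neither was well above background on any of the 6 ungrazed arrays, so only a bound holds: in Cy3 they were at least 17.8-fold and at least 18.1-fold higher in grazed tips. At day 15 their mean log2 ratios were 0.25 and 0.21 in grazed and -0.08 and -0.02 in ungrazed samples. Their means over both days thus rest mainly on day 18. Both calls were lost with Agilent's own ratios, at changes of 4.10 and 4.23 (limma adjusted p = 0.0811 and 0.122). The probe that fell was CUST_1889_PI408257168, with a mean change of -1.69 (SE 0.17, limma adjusted p = 0.032). It stood at -3.17 ± 0.33 in grazed and 0.53 ± 0.48 in ungrazed day 18 samples (SD, n = 2 each), and at 0.35 ± 0.08 and 0.02 ± 0.18 at day 15 (SD, n = 3 each). Its call over both days was lost in 8 of the 10 fits that left out 1 sample, all but those without ungrazed day 15 replicate 3 or ungrazed day 18 replicate 3. The adjusted p in limma then ran from 0.0678 without grazed day 15 replicate 2 to 0.294 without grazed day 18 replicate 3, and the change over the 10 fits from -1.86 to -1.52. It was also lost with median centring (0.0992), the spike-in ratio as a covariate (0.0508), ungrazed day 15 replicates 1 and 2 averaged (0.173) and only probes above background on all 12 arrays (0.232). CUST_1472_PI408257168 and CUST_46204_PI408257168 had lower means, -2.67 and -2.61, but did not pass (limma adjusted p = 0.321 and 0.122). CUST_46204_PI408257168 passed with array weights (0.0261), 12 arrays (0.0077), a replicate block and 12 arrays (0.0157) and without the 3 samples of highest spike-in ratio (0.0341). Agilent's own ratios called 5 probes over both days, 1 higher and 4 lower.

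The effect of grazing differed between the days for 9 probes, 6 with a higher and 3 with a lower change at day 18. Of these, 8 had the larger change at day 18 and 8 were also called there. The majority turned in other fits: with 12 arrays 445 passed, 156 higher and 289 lower, with a replicate block besides 67 higher and 124 lower, with the spike-in ratio as a covariate 8 higher and 12 lower, and with Agilent's own ratios 7, all 7 lower. With median centring 0 passed in limma.

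Between day 15 and day 18, 12 probes differed in grazed tips, 8 higher and 4 lower at day 18, and 2 differed in ungrazed tips, 1 higher and 1 lower. No slide held both days of the same kind of tips, so day and slide were confounded in both comparisons. With 12 arrays the counts were 559 and 471. In grazed tips the majority turned with Agilent's own ratios to 4 higher and 22 lower, with array weights to 117 and 139, with slide as a random block to 17 and 18, with a replicate block and 12 arrays to 177 and 181, and with only probes above background on all 12 arrays to 1 and 3. Median centring gave 7 higher and 0 lower. The ungrazed count was 0 under median centring, scale normalization and the Cy3 channel alone.

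Against the day 0 pool, 3749 probes departed in ungrazed tips, 1385 higher and 2364 lower, and 4986 in grazed tips, 2147 higher and 2839 lower. These comparisons hold the dye difference as well, and the pool was 1 RNA whose own spread was not measured. Median centring gave 215 higher and 934 lower in ungrazed tips and 143 higher and 1265 lower in grazed tips. With only the groups compared in the fit, 0 passed in ungrazed tips and 3618 in grazed tips. In grazed tips the majority turned with array weights (5557 higher and 5043 lower), with 12 arrays (5408 and 5324) and without the 3 samples of highest spike-in ratio (3278 and 2950). In ungrazed tips 27 probes passed without ungrazed day 18 replicate 3, 957 without ungrazed day 18 replicates 1-2 and 395 without ungrazed day 15 replicate 2. In grazed tips 29 passed without grazed day 18 replicate 3, 16 higher and 13 lower, and 48 without grazed day 18 replicates 1-2, 24 either way.

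The pool itself showed differences between slides. Over the 3 slides with more than 1 array, 13313 of 34311 probes differed in Cy5. Between slides 32 and 33, which carried the day 18 groups, 9241 differed, at a median absolute log2 of 0.10. In raw signal, the pool moved by over 1 log2 unit between these slides for 969 of the 34311 probes (2.82%).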

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

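In this part, some tests were chosen after the result was seen. They were the averaging of array pairs and the spreads behind it, the splits at day 15 and day 18, and the tests on the spike-in ratio and control signal. Also chosen after were the fits without 3 samples or with a further pair averaged. So were the pool signal of probes called from Cy3 alone or rising in the pool, and the correlations between samples. The count with 12 arrays was the planned one. The others were set before.

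The effect of grazing differed between day 15 and day 18 for 9 probes in a test of the difference itself. CUST_33803_PI408257168 had a difference of 6.64 log2 units (limma adjusted p = 0.00267) and CUST_33802_PI408257168 one of 6.56 (limma adjusted p = 0.00188), but neither was well above background on any ungrazed day 18 array, so these sizes are not exact. CUST_12858_PI408257168 had -4.67 (limma adjusted p = 0.00525), and was not well above background on any grazed day 18 array, where it was at least 14.8-fold lower in Cy3. CUST_1889_PI408257168 had -4.02 (limma adjusted p = 0.0107). Leaving out 1 sample ended the call of CUST_12858_PI408257168 in 1 of 10 fits (adjusted p = 0.0507 in limma, without ungrazed day 18 replicates 1-2) and that of CUST_1889_PI408257168 in 3 of 10 (0.0598 and 0.0535 without ungrazed day 15 replicate 1 and replicate 2, 0.0955 without grazed day 18 replicate 3). With median centring all 4 calls were lost (0.0587 for both probes of the rising pair and 0.224 for both falling ones) though the differences were 6.15, 6.03, -4.97 and -4.38, in the order above, as they were without the 3 samples of highest spike-in ratio (0.0933 for both of the rising pair, 0.171 for CUST_12858_PI408257168 and 0.198 for CUST_1889_PI408257168) at 6.82, 6.75, -4.39 and -4.26. Agilent's own ratios ended those of CUST_33803_PI408257168 (5.52, adjusted p = 0.485 in limma) and CUST_33802_PI408257168 (5.61, adjusted p = 0.356). That of CUST_1889_PI408257168 also ended with ungrazed day 15 replicates 1 and 2 averaged (0.056) and with only probes above background on all 12 arrays (0.0661). Each of these 4 rests on 2 grazed and 2 ungrazed samples at day 18. Splits of the samples within days do not exclude chance for this count: 8 of 60 splits gave at least as many probes, and the highest other gave 2917. For the 9 probes over both days, 8 of 60 splits gave as many and the highest other gave 2917. These are the same counts, since swapping the day 15 labels turns 1 comparison into the other, so they add no second test. That highest split put ungrazed day 15 replicates 1 and 2 and grazed day 15 replicate 3 with the grazed day 18 samples, and the other day 15 samples with the ungrazed day 18 samples. A count so far above the real one points to a structure of the samples that the grazing labels do not follow.

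At day 15, 10 splits of the 6 samples are too few for a share under 0.05; the real split called 0 probes and so did all 10. At day 18, 3 splits of the 4 samples are too few as well, with 38 probes for the real split (1 of 3 as large) and 0 for the highest other. With 12 arrays the real split of the 6 day 18 arrays called 5453 (1 of 10 as large) and the highest other 0, and 10 splits are again too few.

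The number of probes called at day 18 depended on how 2 pairs of arrays were counted, at 38 or 5453, and with the pairs averaged also on the fit: 4406 with only the groups compared, 4848 with array weights and 1767 without the 3 samples of highest spike-in ratio. The median SD within groups was 0.30 and 0.34 in ungrazed and grazed day 15 samples, and 0.21 and 0.10 in those of day 18. The shared variance thus held more spread than the day 18 samples showed, which goes with more calls when only they were fitted. For the shift with the pairs, repeat arrays of 1 RNA are a candidate explanation. The sample channel of ungrazed day 18 replicates 1 and 2 differed by 0.834 times the spread of the pool (95% interval 0.816 to 0.851), and that of grazed day 18 replicates 1 and 2 by 0.954 times (0.936 to 0.972). The raw signal of the control transcripts differed in the ungrazed pair mainly in Cy3, at 10.47 and 8.87 log2 units against 10.51 and 10.26 in Cy5. It differed less in the grazed pair, at 10.03 and 10.23 against 10.33 and 10.35. The median algal signal in Cy3 moved the other way, at 7.77 and 8.49 in the ungrazed and 7.37 and 6.82 in the grazed pair. These opposite moves argue against 1 labelled product on both arrays of a pair, in which controls and algal RNA would move together. Separate labellings of 1 RNA stay open. Pieces of 1 plant cannot be told apart from repeat arrays, since no label names a plant; the log ratios of the grazed pair correlated at 0.985.

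For the 38 probes called at day 18, the spike-in ratio was added to the model. Their median change was then 1.02 times its value (0.935 to 1.07), with 32 still called. This cannot decide whether labelling yield was a cause. At day 18 the ratio differed by group, at -0.76 and -1.20 in ungrazed and 1.35 and 0.24 in grazed samples. The same fit had also chosen the 38 probes for a small spread within groups, which favours little relation to the ratio. Their pool signal moved between the slides by 0.0457 times the change in the samples at the median (95% interval 0.0306 to 0.0754), but they were chosen on Cy3 over Cy5, which favours such an outcome and leaves a slide effect shared by both dyes undecided for them; for the 39 probes called from Cy3 alone, 24 of them among the 38, the figure was 0.0798 (0.0517 to 0.125), which argues against it there. In 6 probes that rose, the pool signal rose too, to between 1.42% and 6.24% of the Cy3 signal. On slide 33 it was at least 3.27 times the highest on the other slides. Transcript of the common pool, 1 RNA on all arrays, gives no reason for such a rise. But the probes were picked because this signal moved by over 1 log2 unit, which favours the outcome. For 4 of them the share was at least 2.07 times that of the pair CUST_33802_PI408257168 and CUST_33803_PI408257168 on each grazed day 18 array. That pair was set apart for its lowest share, which caps what light carried over in fixed proportion can give. The cap argues against such light as the whole source of the pool signal in these 4 probes, but not as a part of it. Labelled material in both reactions of that slide may be involved, untested. For that pair, carried-over light cannot be told apart from labelled material of that slide's Cy5 reaction, since no other spot as bright had a lower share to bound it, the lowest being 15.5 times as high. An effect of that slide on Cy3 alone and an effect of grazing stay open for all 38, because the slide held only grazed arrays.

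Several day 15 samples correlated with day 18 samples, some across the grazing labels: ungrazed replicate 3 at 0.65 to 0.69 and grazed replicate 2 at 0.55 to 0.59 with the ungrazed ones, and ungrazed replicates 1 and 2 at 0.44 to 0.55 and grazed replicate 3 at 0.62 to 0.65 with the grazed ones, while ungrazed day 15 replicate 3 stood at -0.09 to 0.12 with the others of its group. A swap of that replicate with an ungrazed day 18 sample is argued against, because their correlation of 0.65 exceeded the highest of either with ungrazed day 15 replicates 1 and 2 by 0.391. A low yield of labelled RNA may flatten log ratios: over the 10 samples the spread of log2 ratios fell as the spike-in ratio rose (Spearman rho = -0.903, permutation p = 0.00084; Pearson r = -0.864, permutation p = 0.00042; adjusted p = 0.00168 for both over 4 relations). Without the 2 samples farthest from the median ratio, grazed and ungrazed day 15 replicate 1, r was -0.889, without ungrazed day 15 replicate 3 it was -0.831, and within the 6 day 15 samples -0.859. A correlation between samples does not depend on the scale of their log ratios, so this relation cannot decide why samples correlated across the labels. Ungrazed day 15 replicate 3 itself had the lowest spike-in ratio (-2.13) and the largest spread (1.00), the reverse of flattened log ratios. A difference between plants stays open and untested, and so does a wrong label of ungrazed day 15 replicate 3. A single wrong label would not account for the correlations of the other day 15 samples across the grazing labels.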

How the results depend on the processing

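Counting 12 arrays was the plan and became an alternative once the pairs were averaged. Alternatives that averaged further arrays or neighbouring probes, used the spike-in ratio or left out 3 samples were chosen after the data were examined. So was the fit of only the groups compared with 12 arrays. A replicate block was planned, but its form with 12 arrays was chosen after. Also chosen after were the fits of only the groups compared against the pool, the other normalizations of the whole-profile test and the pool signal without background correction. The cause of each shift was not tested unless said. Counts below are of probes past an adjusted p of 0.05 in limma.

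With each of the 12 arrays counted, the counts were 2 at day 15, 5453 at day 18, 1152 over both days, 445 for the difference between days, 471 and 559 for time in ungrazed and grazed tips, and 10043 and 10732 against the pool. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at 0.06, -0.10 and -0.29 at day 15 and -0.12, -0.16 and -0.16 at day 18. With a replicate block and 12 arrays, 3967 probes passed at day 18, 336 over both days, 191 for the difference, 54 and 358 for time and 9435 and 9900 against the pool. With ungrazed day 15 replicates 1 and 2 averaged too, 11 passed at day 18, 0 for time in ungrazed tips and 1774 against the pool in ungrazed tips.

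With only the groups compared in the fit, 4406 passed at day 18, 0 and 7 for time, and 0 against the pool in ungrazed tips; with 12 arrays these became 13860 at day 18 and 7 and 219 for time. Array weights gave 4848 at day 18, 85 over both days, 2514 for the difference, 203 and 256 for time and 6051 and 10600 against the pool. Slide as a random block, at a correlation within slides of -0.06, gave 71 at day 18, including all 38, and 35 for time in grazed tips. A variance trend together with robust moderation gave 2028 against the pool in ungrazed tips.

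Agilent's ratios gave 5 over both days, 0 and 26 for time and 3190 against the pool in grazed tips. Median centring gave 15 at day 18, 0 for the difference, 0 and 7 for time and 1149 and 1408 against the pool. Scale normalization gave 0 and 30 for time. Cy3 alone gave 15 over both days and 0 and 21 for time. All 38 probes of day 18 kept their direction under each of these. They were called in 12 cases with Agilent's ratios, 13 with median centring, 26 with scale normalization and 24 with Cy3 alone. Without the filter on dim probes 26 passed for time in grazed tips. With only probes above background on all 12 arrays, 1 passed at day 18, 0 over both days, 0 for the difference and 4 for time in grazed tips; fewer probes were tested, which limits what dim probes can show.

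Neighbouring probe numbers averaged gave 1 at day 15, 19 at day 18, 4 over both days, 4 for the difference, 7 for time in grazed tips and 2260 and 2958 against the pool. The spike-in ratio as a covariate gave 20 for the difference, 7 and 25 for time and 7697 against the pool in grazed tips. Without the 3 samples of highest spike-in ratio, 1767 passed at day 18, 2891 over both days, 0 for the difference, 0 for time in ungrazed tips and 9206 against the pool in ungrazed tips.

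Leaving out each sample in turn gave 0 at day 15, 7 to 26 at day 18, 6 to 17 over both days, 6 to 22 for the difference, 0 to 5 and 8 to 44 for time, and 27 to 2757 and 29 to 4727 against the pool. A lone sample was then assumed to vary like the other groups. Each of the 4 day 18 samples, left out, lowered the day 18 count: 11 without ungrazed replicates 1-2, 26 without ungrazed replicate 3, 8 without grazed replicates 1-2 and 7 without grazed replicate 3. Of 402 values of named probes under alternatives, 355 stayed on their side of the threshold, 43 lost and 4 gained a call, and none turned. The 402 include named probes that had not passed to begin with. A probe filtered out of a fit had no value in it. The share that stayed is thus not a measure of how stable the calls were. The whole-profile test gave p = 0.7 to 0.9 (exact permutation) at day 15 and 0.117 to 0.133 over both days under the other normalizations. The gene lists and the averaging of probes of a gene were not run, because the files name no genes.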

Other observations

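The tests of probe numbering and of the distance between spots in this part were set before their results were seen. The description of the 772 probes, the relations to the spike-in ratio and the averaging of neighbours were chosen after.

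Counting 12 arrays, 772 probes were at least 8-fold higher and 26 at least 8-fold lower in grazed tips at day 18. The pool was above background on all arrays for 99.2% of the 772 probes, against 87.9% of all tested probes. Their median log2 ratio to the pool was 2.24 and 2.27 in the grazed and -1.35 and -1.57 in the ungrazed day 18 samples. At day 15 it was 0.88, 0.86 and -2.70 in ungrazed replicates 1, 2 and 3 and -1.08, -0.25 and 1.49 in grazed replicates 1, 2 and 3. These probes thus ranged nearly as widely within the ungrazed day 15 group (-2.70 to 0.88) as between the day 18 groups (-1.57 to 2.27). The spike-in ratio and the first principal component correlated at r = 0.583 (permutation p = 0.0799) and rho = 0.552 (permutation p = 0.106) over 10 samples, each with an adjusted p of 0.106 over 4 relations. Without the 2 samples farthest from the median ratio, grazed and ungrazed day 15 replicate 1, r was 0.720, and without ungrazed day 15 replicate 3, the lowest ratio, it was 0.397.

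Probes with neighbouring numbers changed alike in a way that depends on parity. The day 18 change of an even-numbered probe and of the next number correlated at 0.886 across 13257 pairs, and that of an odd-numbered probe and the next at 0.0892 across 11619 pairs. At day 15 the correlations were 0.839 and 0.0824. This is consistent with numbers having been given in pairs to probes of 1 sequence, a hypothesis that the files cannot settle because they hold no sequences or names. A shared spot region is argued against, since such neighbours lay a median of 153 rows and 25 columns apart. Of the 38 probes called at day 18, 35 had a measured partner, 34 partners had the same direction and 22 were called as well. The called probes may then stand for fewer transcripts than probes: with neighbours averaged, 19 of 21054 units passed at day 18. Such neighbours are CUST_33802_PI408257168 and CUST_33803_PI408257168, CUST_46204_PI408257168 and CUST_46205_PI408257168, and CUST_44292_PI408257168 and CUST_44293_PI408257168. Each of these pairs may stand for 1 transcript.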
